A study of Mus musculus with 8 samples.

How the data were processed

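The series holds 8 arrays from mice of the C57BL/6 strain, 4 of wt and 4 of Irak1-/- CD4+ T cells sorted from mesenteric lymph nodes after cotransfer into Rag1-/- recipients. The labels give a purity above 99.5% after sorting. Total RNA was extracted with TRIzol, labelled with biotin and hybridized by the manufacturer's standard protocol, per the labels. The authors deposited log2 levels of probe sets, the same set for each array. Background correction, summarization and normalization are not given in the sources used here. The values ran from 0.681 to 14.0, array medians lay between 4.25 and 4.31, and no gene centring was seen. No array pair shared identical values at over 50% of the probe sets. Counts or depths do not exist for arrays, so the number of arrays limits the precision.

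Probe sets were joined to genes by the platform's annotation, and symbols were brought up to date by gene identifier for 23328 probe sets with the GRCm38.p6 gene table, which served for names and neighbours alone. Of all probe sets, 23521 carried 1 symbol, 1814 carried several and 16010 were unnamed here. For each of 22180 genes the probe set with 1 symbol and the highest mean level was kept, which mattered for 1082 genes with more than 1 such probe set. Genes with a mean level under the 40th percentile were left out. That left 13308 genes, with a lowest mean level of 3.90. Genes found only on probe sets with several symbols or no name were not analysed here.

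Genotypes were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes on the log2 values with the batch label as a block. The labels pair 1 array of each genotype by batch, and the cells of a pair came from the same pooled recipients. Tests were two-sided, p values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called. Differences are Irak1-/- minus wt, given with a standard error or a 95% confidence interval from the fit.

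The 23 gene lists, the comparisons, the named genes and the alternatives were fixed before the data were examined. Lists were tested with camera, part of limma, which asks whether a list moved relative to the other genes, at a preset correlation of 0.01 and adjusted over the 23 lists. Beside it stand camera with an estimated correlation and fry, which asks whether the genes of a list move, on balance, in 1 direction. Members were counted after adjustment over all genes and after adjustment over the list alone. Genes within 10 Mb of Irak1 or Ptprc were compared with other genes by Fisher's exact test at an unadjusted p under 0.05, since fewer than 20 genes passed the adjusted threshold.

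Genes are named by a rule. It takes Irak1 and Ptprc, up to 12 genes per direction with the largest change among those called and changed the same way in all 4 pairs, and, where fewer than 5 pass, the 8 with the smallest p. It adds up to 4 members of each list with the smallest p, and a panel of 16 genes of homing, T cell subsets and sex chromosomes. Any gene outside the rule is named as such.

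The procedure was tested on simulated data with 8 arrays and 13308 genes. The gene test recovered 79.6% of genes changed by 1 and 96.8% of genes changed by 2 on the log2 scale, in 5 runs of 100 genes each, and called 31 unchanged genes over all runs. Each run held 200 changed genes in total, while in the real data 9 genes rose and 1 fell past the threshold. More changed genes loosen the adjusted threshold, so the recovered shares may be too high for the real data. Camera called 25 of 25 sets of 20 genes shifted by 0.25 and 0 of 100 unshifted sets, and with an estimated correlation it called 16 of the 25. The noise was drawn for each gene independently, so these counts do not cover lists whose genes vary together. In the real data the estimated correlation was 0.62 for the cell cycle genes and 0.33 for the effector and Th1 genes.

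Alternatives were no block, a random block, quantile normalization, median centring, no level filter, a filter at the 60th percentile, the mean of probe sets, every probe set, eBayes with trend and robust settings, leaving out genes near Irak1 and Ptprc, leaving out each pair, the other list tests, and windows of 5 and 20 Mb. A pair of alternatives was added after the data were seen. They are a fit without pairs that leaves out the Irak1-/- array of replicate 3, and the mean myeloid marker level as a covariate. An alternative planned for linear values was not run, since the values were already on the log2 scale.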

Results

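Gene expression was measured on 8 Affymetrix arrays in CD4+ T cells recovered from a mouse model of colitis. In this model naive T cells injected into mice without lymphocytes of their own expand, become effector cells and inflame the gut. Wild-type cells with the CD45.1 form of CD45 and Irak1-/- cells with the CD45.2 form were injected together, in equal numbers, into Rag1-/- mice. After 14 days the CD3+CD4+ cells of each type were sorted from the mesenteric lymph nodes, the nodes that drain the gut. IRAK1 is a kinase that passes signals from IL-1 family receptors and Toll-like receptors on to NF-kappaB. Each of the 4 replicate experiments pooled 2 recipients and gave 1 wt and 1 Irak1-/- array, so the arrays form 4 pairs that share their recipients. The arrays gave log2 levels of probe sets, with array medians between 4.25 and 4.31. The number of arrays, 4 per group, limits the precision of every value.

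The 8 arrays were alike across genes, and the Irak1-/- array of replicate 3 stood apart from the rest. Correlations among the other 7 arrays ran from 0.969 to 0.981, while that array correlated with the others at 0.950 to 0.957. It lay at 37.6 on the first principal component, which held 34.5% of the variance. The second component held 14.7%. Levels of Xist, the RNA that silences an X chromosome in female cells, were 10.74 ± 0.157 (SD, n = 4) in wt and 10.70 ± 0.132 in Irak1-/- arrays. The Y-linked genes Eif2s3y, Kdm5d and Uty had mean levels between 2.00 and 2.57 in both groups, under the level needed for testing.

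**Figure D1:**
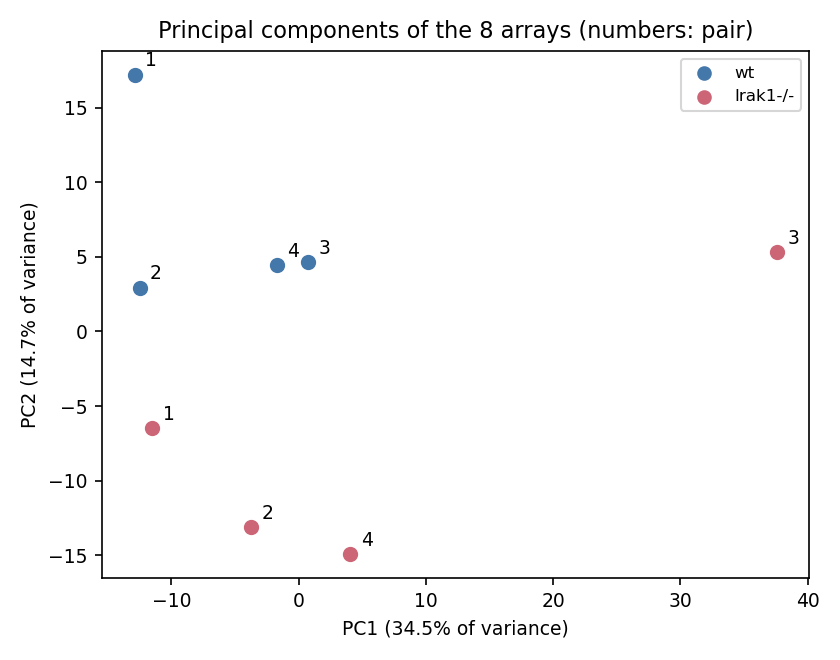
Principal components of the 8 arrays, with the score on component 1 (34.5% of the variance) on the horizontal axis and on component 2 (14.7%) on the vertical axis, in log2 units. Each point is 1 array, coloured by genotype and numbered by replicate, and the Irak1-/- array of replicate 3 lies at 37.6 on component 1, away from the other 7.

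Irak1 was the gene removed, and its own level did not separate the groups. Its probe set, 17542546 on chromosome X, read 6.77 ± 0.332 (SD, n = 4) in wt and 6.84 ± 0.167 in Irak1-/- arrays. The log2 difference was 0.07 (SE 0.129, limma adjusted p = 0.953), with a higher level in 2 of 4 pairs. The part of the gene that was deleted is not given in the sources used here, so this level does not check the genotype. Ptprc, which encodes CD45 itself, read 10.90 ± 0.0753 in wt and 11.01 ± 0.0581 in Irak1-/- arrays, a log2 difference of 0.11 (SE 0.107, adjusted p = 0.918).

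The main question was which genes differ between Irak1-/- and wt T cells that spent the same 14 days in the same recipients. Lyz2, Tyrobp, Fcer1g and H2-Aa, which are markers of myeloid cells, and 5 further genes rose on the Irak1-/- arrays, while Ctse, the gene of the intracellular protease cathepsin E, fell to a 15.3-fold lower level. Lyz2, the lysozyme of macrophages and neutrophils, read 3.84 ± 1.02 (SD, n = 4) in wt arrays and rose by a fitted 4.16 (SE 0.302, adjusted p = 0.00161) on the log2 scale, or 3.90 without pair 2, whose wt array read 2.34. Chil3, a chitinase-like protein secreted by macrophages, read 4.07 ± 0.807 in wt arrays and rose by a fitted 2.77 (SE 0.254, adjusted p = 0.00447). Both wt means lay under every array median, although Chil3 read 4.45 to 4.51 in 3 of 4 wt arrays. Background is not given for these arrays, so how far such levels lie above it is unknown and the size of these differences is uncertain. Saa3, an acute phase protein, rose 6.62-fold (95% confidence interval 4.83 to 9.08, adjusted p = 0.00161). Of 13308 genes tested, 9 rose and 1 fell at an adjusted p under 0.05, and all 10 moved the same way in 4 of 4 pairs.

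Receptor adaptors, antigen presentation and inflammatory mediators made up the other genes that rose. Tyrobp and Fcer1g, which couple activating receptors of myeloid and natural killer cells to kinases, rose 5.54-fold (adjusted p = 0.00176) and 3.70-fold (adjusted p = 0.00176). Clec4a3, a lectin receptor of myeloid cells, rose by a fitted 1.76 on the log2 scale (SE 0.225, adjusted p = 0.0420) from a wt level of 3.03 ± 0.241. H2-Aa, a chain of the MHC class II molecule, rose 3.34-fold (adjusted p = 0.00317). Cxcl9, a chemokine induced by interferon-gamma that attracts cells with the receptor CXCR3, rose 2.83-fold (adjusted p = 0.00892), and Il1b, the cytokine IL-1 beta, rose by a fitted 1.45 on the log2 scale (SE 0.143, adjusted p = 0.00672) from 4.05 ± 0.219. The wt means of Clec4a3 and Il1b also lay under every array median, so the same holds for them. In pair 2 the wt array read 3.66 for Saa3 and 3.88 for H2-Aa, likewise under every array median. Their differences are of uncertain size too. The probe sets of the 9 genes were 17245223 for Lyz2, 17408897 for Chil3, 17491193 for Saa3, 17476364 for Tyrobp, 17229658 for Fcer1g, 17462738 for Clec4a3, 17343813 for H2-Aa, 17449710 for Cxcl9 and 17391565 for Il1b.

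The calls of 4 of these genes were lost when single pairs or the pairing were left out, while their differences kept their direction there. Clec4a3 had an adjusted p of 0.255 without pair 2, 0.0831 without pair 3 and 0.180 without pair 4, with log2 differences of 1.83, 1.55 and 1.61, and also missed with quantile normalization (0.0672) and without the level filter (0.101). Cxcl9 had 0.0519 without pair 1 and 0.115 without pair 2, with differences of 1.54 and 1.49. Il1b had 0.0519 without pair 2 and 0.0513 without pair 4, with 1.52 and 1.35. Chil3 had 0.116 in a fit without pairs, with the same 2.77. The number of genes that rose was 16 without pair 1, and 8 of the 9 were among them. With every probe set tested in place of 1 per gene, no gene passed, the lowest adjusted p being 0.0625.

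**Figure D2:**
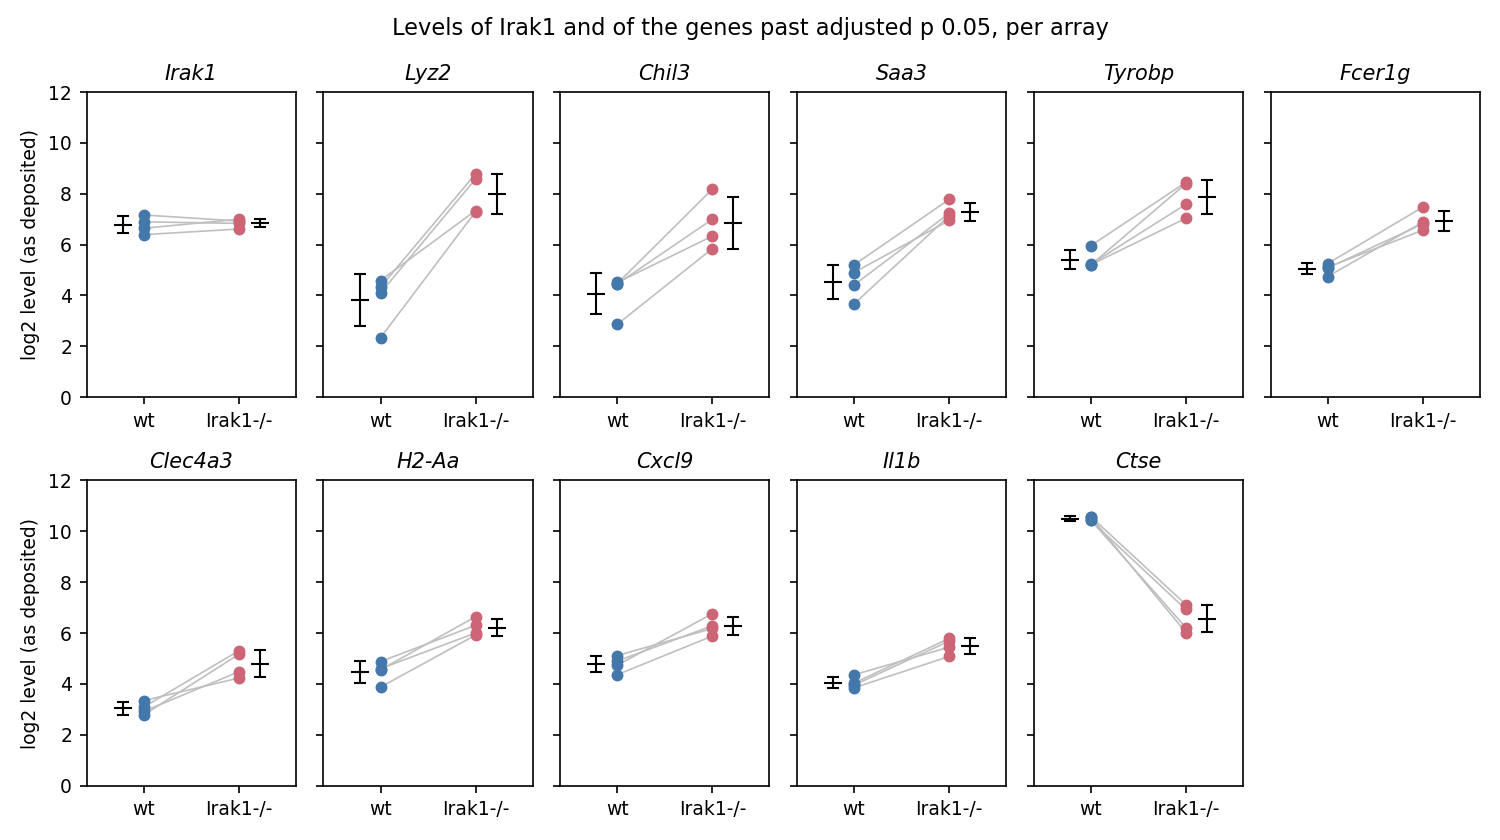
Log2 levels (vertical axis) of Irak1 and of the genes that passed the test, each point 1 array, with wt (blue) and Irak1-/- (pink) arrays of a pair joined by a line and black bars for the mean and SD of 4 arrays. Mean levels of Lyz2 differ by 4.16, and Ctse has 10.51 in wt and 6.57 in Irak1-/- arrays.

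Ctse stood alone among the genes that fell. Its probe set, 17217035 on chromosome 1, read 10.51 ± 0.0802 (SD, n = 4) in wt and 6.57 ± 0.536 in Irak1-/- arrays. That is a log2 change of -3.93 (SE 0.189, adjusted p = 0.000133) and a 15.3-fold lower level (95% confidence interval 11.4 to 20.6), seen in 4 of 4 pairs and under each left-out pair. Ctse lies within 10 Mb of Ptprc, the gene whose alleles mark the transferred populations. The genes next in order of p, each lower in all 4 pairs, did not pass. Ptprv, annotated as a phosphatase pseudogene, had a log2 difference of -0.85 (adjusted p = 0.0559), and Nccrp1 -0.75 (adjusted p = 0.0937). Nr4a1, a nuclear receptor induced by antigen receptor signals, had -0.76 (adjusted p = 0.162). Differences were -0.66 for Dvl2, a Wnt signal relay, -0.66 for Ppp1r3g, a regulator of glycogen synthesis, -0.62 for Gm7609 and -0.52 for Tmem37, with adjusted p between 0.158 and 0.223.

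Few genes outside these passed a looser threshold. An unadjusted p under 0.05 was reached by 892 genes, 383 higher and 509 lower, where chance gives 665.4. At an adjusted p under 0.1 there were 19 higher and 3 lower. All 4 pairs moved the same way for 1886 genes, or 14.2%, where chance gives 12.5%. The median log2 change was -0.03.

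Genes beside the marker gene and beside the deleted gene were compared with all others, because congenic and targeted alleles can carry flanking DNA of another strain. Within 10 Mb of Ptprc, 11 of 101 tested genes (10.9%) had an unadjusted p under 0.05, 4 higher and 7 lower, against 6.66% elsewhere. The shares did not differ by a two-sided Fisher's exact test (p = 0.105, adjusted over both regions 0.21). Among the 11 were Ctse, Ptprv, Ube2t, a ubiquitin-conjugating enzyme of DNA repair, with a log2 difference of 0.72 (adjusted p = 0.121), and Cd55, a complement regulator, with -0.65 (adjusted p = 0.426); Ube2t and Cd55 were chosen after their values were seen. Within 10 Mb of Irak1, 3 of 58 genes (5.17%) reached that p, against 6.70% elsewhere (Fisher's exact p = 1).

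Gut homing is named in the title of the series, and its receptors did not differ as a group. Among 20 tested receptors and ligand enzymes for gut and tissue homing, none passed over all genes, and 1 was higher when adjusted over the list alone. That gene was Itgae, the CD103 integrin chain that binds E-cadherin on epithelium, with a log2 difference of 0.61 (SE 0.141, adjusted p over the list 0.0434, over all genes 0.352). Ccr9, the receptor for the small intestinal chemokine CCL25, had a difference of -0.11 (adjusted p = 0.925). Itga4 and Itgb7, the chains of the integrin that binds the gut vessel ligand MAdCAM-1, had -0.09 (adjusted p = 0.948) and -0.04 (adjusted p = 0.967). Cxcr3, a receptor of Th1 cells, had -0.03 (adjusted p = 0.987). St3gal4, Gcnt1 and Ccr4 had -0.36, 0.39 and 0.41, with adjusted p between 0.670 and 0.778. The list's median was -0.06, its mean 0.01 and the direction of its camera test upward (adjusted p = 0.889, or 0.973 with an estimated correlation), and 2 of 4 pair means were positive.

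Effector genes fell as a list on the Irak1-/- arrays, by a median of -0.18 on the log2 scale over 31 genes (camera adjusted p = 0.000543). That call was lost at adjusted p = 0.668 with an estimated correlation. No member passed over all genes, and 5 were lower when adjusted over the list alone, with 0 higher. These were the cytotoxic granule genes Gzmk (-0.67), Gzma (-0.49) and Prf1 (-0.49), the early activation marker Cd69 (-0.51) and the death ligand Fasl (-0.58). Prf1 was chosen after its value was seen. Pair means were 0.04, -0.20, -0.39 and -0.18, so 3 of 4 were negative and the lowest came from pair 3, whose Irak1-/- array stood apart. Without pair 3 the median was -0.09 (adjusted p = 0.0327), and without that array, in a fit without pairs, it was -0.03 (adjusted p = 0.152). With pairs 1, 2 and 4 left out in turn, the medians were -0.285, -0.234 and -0.166. On the same arrays the myeloid markers had a mean change of 0.92. The NK, ILC and CD8 T cell markers had a mean of -0.19, negative in 4 of 4 pairs, which did not pass as a list (adjusted p = 0.0643), with Klrd1 at -0.55, Klrk1 at -0.51, Klre1 at -0.66 and Cd8a at -0.55. Of the 11 tested, 7 had negative and 4 had positive differences, among the latter Cd8b1 at 0.31, and the median was -0.05. Cd8b1 was chosen after its value was seen.

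NF-kappaB targets, the genes downstream of the pathway that IRAK1 serves, fell as a list by a median of -0.18 over 24 genes (adjusted p = 0.00124), with negative means in 4 of 4 pairs, from -0.25 to -0.10. With an estimated correlation the call was lost at adjusted p = 0.317. No member passed over all genes, while 6 were lower and 1 higher when adjusted over the list alone. Lower were the cytokine gene Tnf (-0.50), the feedback regulators Nfkbia (-0.43), Nfkbiz (-0.46) and Zc3h12a (-0.47), the stress response gene Ier3 (-0.50) and the adhesion molecule Icam1 (-0.44). Higher was Il2, the T cell growth factor, at 0.64. Nfkbia, Zc3h12a and Icam1 were chosen after their values were seen. In the same pairs the myeloid markers had means between 0.62 and 1.08, and the NK, ILC and CD8 T cell markers, which did not pass as a list (adjusted p = 0.0643), had -0.07, -0.33, -0.13 and -0.22.

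Th1 genes fell as a list by a median of -0.18 over 16 genes (adjusted p = 0.0202), and the call was lost at adjusted p = 0.668 with an estimated correlation. Adjusted over the list alone, Fasl, Tnf and Ifng were lower and Il2 was higher, and none passed over all genes. Ifng, the cytokine that defines Th1 cells, had a log2 difference of -0.62 (SE 0.152, adjusted p over all genes 0.404) and was lower in 4 of 4 pairs. Tbx21, the Th1 master regulator, had -0.23 (adjusted p = 0.891). The pair means were -0.01, -0.07, -0.43 and -0.11, and the adjusted p was 0.478 without pair 3, and 0.152 in a fit without pairs that left out its Irak1-/- array. The medians in these fits were -0.05 and -0.09. The myeloid mean in pair 3 was 0.99.

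Genes of follicular helper T cells, which help B cells in germinal centres, rose as a list by a median of 0.16 over 12 genes (adjusted p = 0.000142), and 11 of the 12 had positive differences. The call was lost at adjusted p = 0.317 with an estimated correlation. Pair means were 0.24, 0.01, 0.20 and 0.34, all 4 positive, beside myeloid means of 0.62, 0.99, 0.99 and 1.08. With each pair left out in turn, the median ran from 0.15 (without pair 4) to 0.25 (without pair 2). No member passed over all genes or adjusted over the list alone. Cd200, a surface glycoprotein of activated lymphocytes, had a difference of 0.49 (adjusted p = 0.580), and Cxcr5, the receptor that leads cells to B cell follicles, had 0.46 (adjusted p = 0.642). Btla, an inhibitory receptor, and Il21, the cytokine of follicular and Th17 cells, had 0.30 and 0.34.

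Th17 genes rose as a list by a median of 0.08 over 19 genes (adjusted p = 0.0151), and the call was lost at adjusted p = 0.668 with an estimated correlation. No member passed over all genes, and 0 were higher or lower when adjusted over the list alone. Il1r1, the IL-1 receptor that sustains Th17 cells, had the smallest p, with a log2 difference of 0.50 (SE 0.126, adjusted p = 0.404) and a higher level in 4 of 4 pairs. Il22, a cytokine that acts on epithelium, had 0.50, Ccr6, a chemokine receptor of Th17 cells, 0.38, and Il17a 0.24 (adjusted p = 0.898). Pair means were 0.25, -0.12, 0.01 and 0.34, and the call was lost without pair 1 (adjusted p = 0.141) and without pair 4 (0.215), where the medians were 0.02 and 0.06. Without pair 3 the median was 0.15 (adjusted p = 0.00979). In a fit without pairs that left out the Irak1-/- array of replicate 3 it was 0.16, and the adjusted p was 0.0524. Myeloid means in those pairs were 0.62 and 1.08.

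Genes of naive and central memory cells rose as a list by a median of 0.04 over 17 genes (adjusted p = 0.0151), and the call was lost at adjusted p = 0.317 with an estimated correlation. No member passed over all genes or adjusted over the list alone. Ccr7, the receptor that brings cells into lymph nodes, had a log2 difference of 0.43 (SE 0.113, adjusted p = 0.430) and was higher in 4 of 4 pairs, as were Id3 (0.37), a transcriptional inhibitor, and Igfbp4 (0.28). Il6ra, the IL-6 receptor, had 0.26. The call was lost without pair 1 (adjusted p = 0.121), pair 2 (0.0570) or pair 4 (0.0606), and in a fit without pairs (0.0656, median 0.04). With those pairs left out in turn, the medians were 0.04, 0.07 and 0.03. Without pair 3 the median was 0.11 (adjusted p = 0.00521), and in the fit without pairs that left out its Irak1-/- array it was 0.07 (adjusted p = 0.163). Pair means were 0.15, 0.08, -0.02 and 0.15, so 3 of 4 were positive, beside a mean of 0.92 for the myeloid markers.

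Cell cycle genes fell as a list by a median of -0.12 over 44 genes (adjusted p = 0.0151), and the call was lost at adjusted p = 0.813 with an estimated correlation. The pairs were split. Their means were 0.18, -0.27, -0.38 and 0.02, so 2 of 4 were negative, and the call was lost without pair 2 (adjusted p = 0.523) or pair 3 (0.802). With each pair left out in turn, the median ran from -0.01 (without pair 3) to -0.23 (without pair 1). In a fit without pairs and without the Irak1-/- array of replicate 3, the median turned to 0.06 (adjusted p = 0.248). No member passed over all genes or adjusted over the list alone. Bub1b, a spindle checkpoint kinase, had a difference of -0.39 (adjusted p = 0.708), Kif20a, a mitotic motor, -0.31, Tpx2, a spindle assembly factor, -0.26, and Foxm1, a regulator of mitotic genes, -0.25. Myeloid means in pairs 2 and 3 were 0.99 and 0.99.

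**Figure D3:**
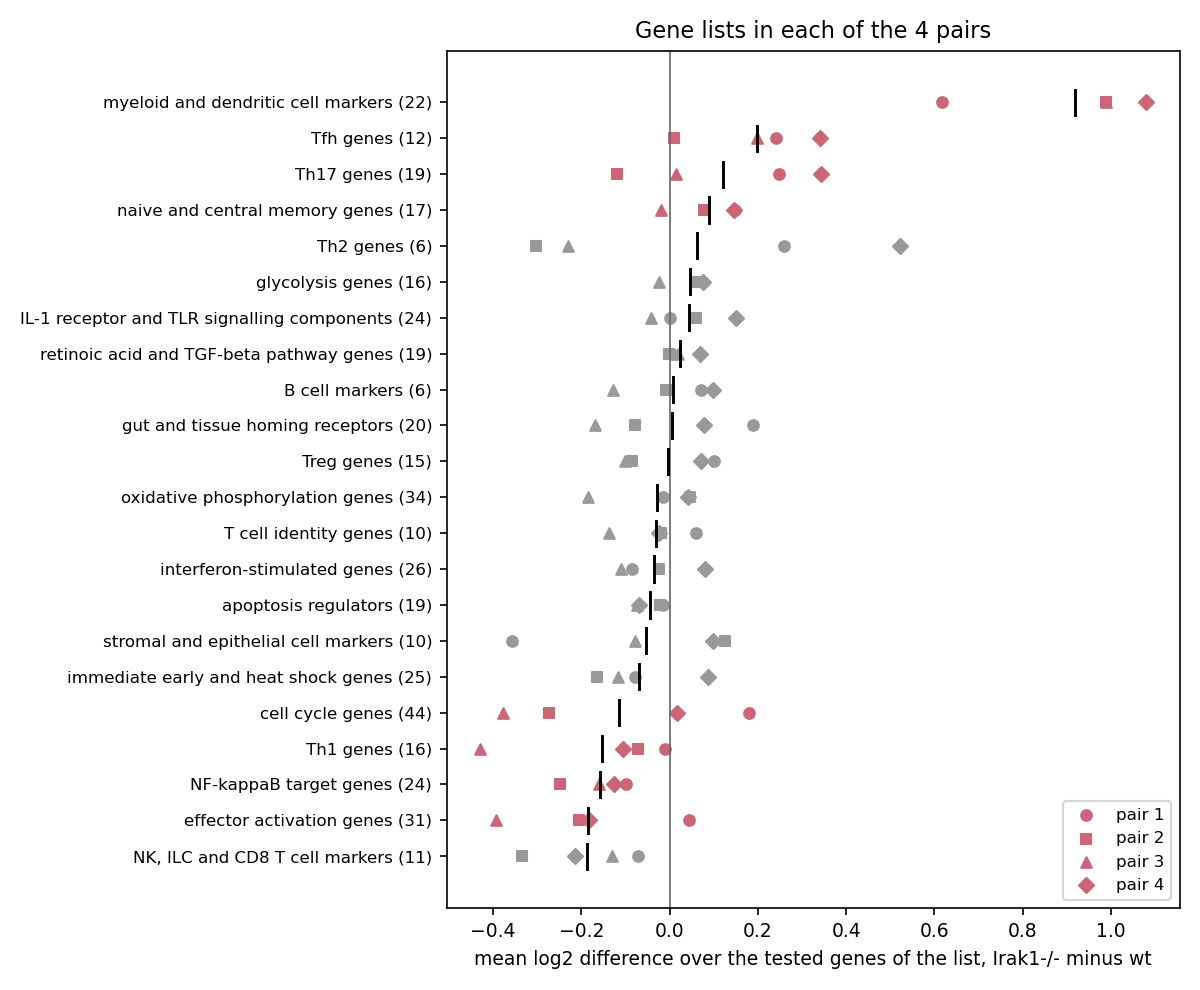
Mean log2 difference, Irak1-/- minus wt (horizontal axis), of each gene list with at least 2 tested genes, with the number tested in brackets. Each point is 1 of the 4 pairs, with a shape per pair, each black bar is their mean, and pink marks the 8 lists with a camera adjusted p under 0.05, of which the myeloid and dendritic cell markers lie between 0.62 and 1.08.

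Other T cell programmes did not pass. Th2 genes (6 tested) had a median of 0.01 (adjusted p = 0.269, or 0.756 with an estimated correlation), which median centring turns below 0. Treg genes (15 tested) had a median of -0.06, a mean of 0.00 with negative sign and an upward test (adjusted p = 0.618), and 1 was higher when adjusted over the list alone, Itgae. Foxp3, the Treg master regulator, had a difference of -0.06 (adjusted p = 0.960). Pathway genes of TGF-beta and of retinoic acid, which imprints gut homing, had a median of 0.03 over 19 genes (adjusted p = 0.404), with Itgae again higher over the list alone.

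Signalling, stress and metabolic lists gave no call either. Components of IL-1 receptor and Toll-like receptor signalling (24 tested) had a median of 0.00, with negative sign, a mean of 0.04 and an upward test (adjusted p = 0.164); Il1r1 and Tlr2, a receptor for bacterial lipoproteins, had differences of 0.50 and 0.39. Interferon-stimulated genes (26 tested) had a median of -0.05 (adjusted p = 0.889). Immediate early and heat shock genes (25 tested) had a median of -0.11 (adjusted p = 0.269), and Nr4a1 was lower when adjusted over the list alone. Apoptosis regulators (19 tested) had -0.04 (adjusted p = 0.827), glycolysis genes (16 tested) 0.04 (adjusted p = 0.180) and oxidative phosphorylation genes (34 tested) -0.02 (adjusted p = 0.934). No member of these lists passed over all genes.

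Markers of other cell types were measured because a lymph node sort can hold them. Myeloid and dendritic cell markers rose as a list by a median of 0.61 over 22 genes (adjusted p = 2.16e-22), with means above 0 in 4 of 4 pairs. The call was lost at adjusted p = 0.123 with an estimated correlation, and fry gave an adjusted p of 0.0370. Over all genes 4 rose, Lyz2, Tyrobp, Fcer1g and H2-Aa, and adjusted over the list alone 13 were higher and 1 lower. S100a8, a calcium-binding protein of neutrophils, had a log2 difference of 2.62 (adjusted p = 0.0635), H2-Ab1, the MHC class II beta chain, 1.77 (0.0798), and the macrophage growth factor receptor Csf1r 0.72 (0.471). Itgax, the dendritic cell integrin CD11c, had -0.59 (0.501). Cst3, a protease inhibitor abundant in dendritic cells, read 9.79 in both groups. S100a8, H2-Ab1, Csf1r, Itgax and Cst3 were chosen after their values were seen. The CD45 allele of the recipients' own cells is not given in the sources used here.

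The remaining cell type lists did not pass. Markers of NK, ILC and CD8 T cells (11 tested) had a median of -0.05 (adjusted p = 0.0643, or 0.462 with an estimated correlation), and passed without pair 1 (0.0319). Adjusted over the list alone, the NK receptor genes Klrd1 (-0.55) and Klrk1 (-0.51) were lower. B cell markers (6 tested) had a median of 0.03 (adjusted p = 0.641), stromal and epithelial markers (10 tested) -0.05 (adjusted p = 0.827). The only erythroid marker tested, Slc4a1, had -0.01, with an upward test (adjusted p = 0.934). T cell identity genes (10 tested) had a median of -0.05 (adjusted p = 0.889); Cd4 had a difference of -0.12, Lat -0.08, Thy1 -0.06 and Cd28 0.06. Of the 23 lists, 8 passed, 4 up and 4 down, and 0 passed with an estimated correlation.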

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

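The fit without pairs that leaves out the Irak1-/- array of pair 3 and the tests of a lower T cell share were chosen after the list results were seen, as was the use of the count of lists without pair 3 as a test of that array. Leaving out each pair and the comparisons with other splits of the arrays were planned. Each group of 4 arrays was searched for an array whose gap to its nearest neighbour, as a share of the group's range, exceeded Dixon's 95% limit for 4 values. Of 112 groups 10 did so, where chance gives about 1 in 20, or 5.6.

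The Irak1-/- array of replicate 3 stood apart in its mean correlation with the other Irak1-/- arrays, 0.957 against 0.970 to 0.971, a gap share of 0.903. Among lists, the wt array of replicate 4 had an IL-1 receptor and TLR level of 6.27 against 6.40 to 6.41 (0.916). The retinoic acid and TGF-beta list read 5.93 in the wt array of replicate 1 against 6.00 to 6.02 (0.844). Chil3 read 2.86 in the wt array of replicate 1 against 4.45 to 4.51 (0.964), and Tyrobp read 5.96 in the wt array of replicate 3 against 5.20 to 5.23 (0.960). In that same wt array Ptprc read 11.01 against 10.84 to 10.87 (0.845) and Nr4a1 7.98 against 8.31 to 8.36 (0.863). In the wt array of replicate 2, Gm7609 read 5.18 against 5.79 to 5.84 (0.920) and Itgb7 8.95 against 8.71 to 8.74 (0.887). The Y-linked Eif2s3y read 2.48 in the Irak1-/- array of replicate 4 against 1.83 in the other 3 (0.998).

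Without pair 3, 6 of the 8 lists passed in the same direction, and the Th1 and cell cycle calls were lost. In a fit without pairs, leaving out only the Irak1-/- array of pair 3 took the adjusted p of the effector list from 0.00639 to 0.152 and its median from -0.176 to -0.0262, so that array may carry part of the effector call. The adjusted p of the Th17 list went from 0.0417 to 0.0524 and that of the naive list from 0.0656 to 0.163, but their medians were larger without it (0.16 against 0.08, and 0.07 against 0.04). The Tfh genes had a mean of 0.197, with a lowest pair mean of 0.009. A lower share of T cell RNA would lower these genes, so it does not account for their rise. Their mean had already been seen, so it is no test of such a share. For the effector genes such a share stays open. The T cell identity genes had a median of -0.0461 and a lowest change of -0.118, against a median of -0.176 for the effector genes. A permutation test did not separate the lists (p = 0.18). The real pairing gave 8 lists. The other splits that part all 4 pairs gave between 1 and 6 lists each, and none of them called a gene. Splits that swap a single pair keep most of the real contrast, and the split with 6 lists was of this kind. Those that balance genotype gave 1, 1 and 3 lists, so camera at the preset correlation called some lists there too. The 8 splits that part all 4 pairs are too few for a share under 0.05, with 1 as large, the real split.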

How the results depend on the processing

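Over 132 results and 2060 alternative values, list tests stayed on the same side of the threshold without reversing a call in 366 cases. They were weaker in 37, stronger in 5 and reversed in 5. Named genes stayed so in 1572 cases, with 31 weaker, 5 stronger and 1 reversed. The 366 and 1572 cases include 93 sign changes among values past the threshold in neither fit. Counts and neighbour shares stayed within range in 26 cases and moved in 12. Where no cause is given, the cause was not tested.

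The number of genes that rose, 9, ran from 6 to 16 when each pair was left out. It was 14 with a random block and 14 with median centring, and 0 with every probe set and 0 with the myeloid covariate. The number that fell, 1, was 2 with a random block, median centring or the 60th percentile filter, 3 with trend and robust settings, and 0 with every probe set or the covariate. It was 0 without genes near Irak1 and Ptprc, where Ctse itself is left out. With every probe set 24800 were tested and the prior degrees of freedom fell from 5.69 to 2.73. The covariate had a within-pair correlation of 0.982 with genotype and widened the unmoderated standard error 5.27-fold, so that fit separates little. In it Clec4a3 turned to -0.90.

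For lists, the values are adjusted p. Leaving out each pair gave 0.00521 to 0.121 for naive genes, 0.00772 to 0.478 for Th1, 0.000386 to 0.215 for Th17, 1.93e-06 to 0.802 for cell cycle and 0.0319 to 0.232 for NK, ILC and CD8 markers. Without the block, naive genes had 0.0656 and cell cycle 0.148, and with a random block 0.0553 and 0.122. With every probe set, naive genes had 0.0948 and Th17 0.119. The estimated correlation gave 0.317 for naive, Tfh and NF-kappaB genes, 0.668 for effector, Th1 and Th17, 0.813 for cell cycle and 0.123 for myeloid markers. The estimates themselves were 0.063 for myeloid markers and -0.022 for naive genes. A correlation above the preset 0.01 therefore does not account for the lost naive call. In the simulation, whose genes were independent, the estimated form also called fewer shifted sets, 16 of 25 against 25 of 25. A lost call under it therefore need not mean that the genes of a list vary together. Fry gave 0.468 for naive and effector genes, 0.470 for Th1, 0.640 for Th17, 0.331 for Tfh, 0.729 for cell cycle and 0.189 for NF-kappaB. The NK, ILC and CD8 markers passed with no level filter (0.0449), the 60th percentile filter (0.0133) and trend and robust settings (0.0263).

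Both alternatives added after seeing the data changed lists. Without the Irak1-/- array of replicate 3 and without pairs, naive genes had 0.163, effector 0.152, Th1 0.152 and Th17 0.0524, and cell cycle reversed (0.248). With the covariate, naive, Th17 and Tfh genes had 0.608 and myeloid markers 0.828. There effector (0.0287), Th1 (0.608), cell cycle (9.21e-05) and NF-kappaB genes (0.873) reversed, and stromal and epithelial markers passed (0.000677). Signal over background is not given for these arrays, so what background hides in genes at low levels is unknown.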

Other observations

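The grouping of genes by RNA class, the added macrophage list, the tests of other cell types, of T cell share and of genes near Ptprc beyond the planned Fisher's exact test were chosen after the results were seen, as was the reading of that Fisher's exact test against Ctse.

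Small nucleolar RNAs, which guide chemical modification of ribosomal and other RNAs, were higher as a class on the Irak1-/- arrays. Of 67 tested, 19 had an unadjusted p under 0.05 and all 19 were higher. Their median log2 difference was 0.22, and the pair means were 0.14, 0.15, 0.55 and 0.18, all 4 above 0. The camera p was 4.88e-17, or 1.95e-16 adjusted over 4 RNA classes, and 1.35e-07 without pair 3, which had the highest mean. The Irak1-/- array of pair 3 was the one that stood apart from the other arrays. With an estimated correlation the p was 0.0519, or 0.12 adjusted. Of the other classes, microRNAs (159 tested) had a median of 0.01 (adjusted p = 0.0869), long non-coding RNAs (717 tested) -0.02 (adjusted p = 0.41) and protein-coding genes (12040 tested) -0.03 (adjusted p = 0.0268, or 0.175 with an estimated correlation, and an unadjusted p of 0.261 without pair 3).

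The rise of Lyz2, Tyrobp, Fcer1g and other myeloid genes may come from myeloid cells in the CD45.2 sort, which would take up the recipients' own cells if these carry CD45.2, an allele not given in the sources used here, although the CD3 and CD4 gates would remove such cells and the labels give a purity above 99.5%. Of 35 further macrophage and monocyte genes, 24 were tested, none of them on a list fixed beforehand and 19 of them above every array median in wt cells; their median log2 difference was 0.186, with means above 0 in all 4 pairs (0.126 to 0.386, camera p = 4.37e-11, or 0.0186 with an estimated correlation). Of the 24, 21 had positive and 3 had negative differences. Pirb (1.11), Aif1 (1.08) and C1qb (0.63) led the positive ones, none past the test over all genes. Of the abundant members Psap (level 8.48) had 0.13 and Ctsb (7.89) 0.15. The 3 negative ones were Lilrb4a (10.35) at -0.17, Plek (7.60) at -0.34 and Lgals3 (6.45) at -0.15. The 17 B cell, stromal, epithelial and erythroid markers had a median of -0.0141, below that of the myeloid markers (permutation p = 0.00375). This comparison cannot decide whether cells of every other type entered alike. The recipients have no B cells of their own, and the sort was by CD45, a protein of white blood cells, so these types had little chance to enter. The NK, ILC and CD8 T cell markers, with a mean of -0.188, were not part of it. The permutation treats genes as independent, both medians had been seen before, and the wt means of the B cell, stromal, epithelial and erythroid lists were low, from 3.93 to 4.91. A change inside the Irak1-/- T cells stays open, since no level in bulk RNA could tell it from myeloid cells in the sort. The lowest pair mean of the myeloid markers, 0.617, thus has no bearing on it.

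The fall of Ctse was weighed against T cell share and against DNA linked to the CD45 allele. A lower share of T cell RNA is argued against, since the lowest log2 change of any T cell identity gene was -0.118 and the interval of Ctse ended at -3.50. The wt cells carry CD45.1, an allele of Ptprc usually crossed in with flanking DNA of another strain, and Ctse lies near it, so strain DNA may account for Ctse and cannot be told apart from the loss of Irak1, because the CD45 allele coincides with genotype; the planned Fisher's exact test gave p = 0.105. After it missed, a permutation of single genes without Ctse gave a one-sided p of 0.00137, with 3 of the 30 genes with the smallest p near Ptprc where 0.225 would be by chance, but it treats neighbours as independent and keeps genes already noticed. A stricter comparison left out the 4 genes near Ptprc with the smallest p. The other 97 had a median rank of p at 40.3%, matched or passed by 23 of 886 overlapping windows elsewhere (2.6%), against 39.0% and 14 windows with all 101. Cd55, whose value had also been seen, stayed among the 97, so this comparison is not free of genes already noticed.

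Chance was also set against the gene calls. Of the 8 splits that part all 4 pairs, the real one called 10 genes and the highest other called 0, and 8 splits are too few for a share under 0.05. In the fit without pairs the real split called 11 genes, the highest of the other splits called 0, and 1 of 35 splits, the real one, gave as many. Those 35 include splits that do not part the pairs that share recipients, so chance is not taken as excluded.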
